A study of Sus scrofa with 6 samples.

How the data were processed

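Peripheral blood mononuclear cells of 3 crossbred piglets, 8 weeks of age, had been frozen, thawed, stained for CD14 and CD163 and sorted into CD14low-CD163high and CD14high-CD163low monocytes, per the labels' protocols. Total RNA (500 ng) was amplified and 5.5 µg of cDNA was labelled with biotin and hybridised, 1 array per sample, which gave 6 arrays in 2 groups of 3. The descriptions in the labels give the pig of each array, so the 2 arrays with the same number came from the same animal. The p-values of single genes rest on the spread between arrays of different animals, which holds differences between arrays as well. Without a block the main fit treats the 2 arrays of a pig as independent. The p-values of gene lists from camera compare members with the other genes and do not measure the spread between animals.

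The deposited table holds probe-set intensity values of the 6 arrays. RMA and limma are named in the submitters' processing notes, without versions or roles; the software for RMA, the probe-set definition and any filter are not given in the sources used here. RMA subtracts background, equalises the distribution of intensities between arrays and summarises probes. This compresses differences of dim probe sets and leaves no absolute unit. The table mixes 2 scales: the first 186 rows, mostly array controls, hold log2 values, and in the other 47659 rows the log2 of every deposited value was a whole multiple of 0.0001 within 0.000001, so these rows are antilogs. The log2 of the later rows was taken and the first rows were kept. The medians of the deposited columns lay between 8.726 and 9.856, and after the log2 between 3.13 and 3.31. A single scale across the probe sets follows from this rule and was not stated by the authors.

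All 47845 rows were read and the 123 array control probe sets were left out of the tests, which left 47722. Of these 26426 had exactly 1 gene symbol in the array's annotation, 0 had several and 21296 had none. Symbols are those of the array's design and can be old; 13408 of the 13755 distinct symbols were found in the current RefSeq (Sscrofa11.1) or Ensembl name tables. The array's genome build is not given in the sources used here, so no coordinates are printed. A gene was represented by its probe set with the highest mean over all 6 arrays.

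The main test was limma (version 3.58.1, R 4.3.3), lmFit and eBayes without trend or robust options, CD163high against CD163low with no block, two-sided, with Benjamini-Hochberg adjustment over all 47722 probe sets and a threshold of 0.05. The fit with the pig as a block was an alternative, since no source used here says that the authors blocked on the pig. As a check of the pairing, deviations from the group means were correlated. The 2 arrays of a pig correlated at -0.20, 0.67 and 0.26 in pigs 1, 2 and 3. The highest correlation between arrays of different pigs was 0.60, between CD163high of pig 3 and CD163low of pig 1. Those 2 arrays had the highest mean background control signal, at 3.67 and 3.29, so this check is not free of differences between arrays. EIF1AY, the 1 measured Y-linked gene, differed by 4.07 and -2.31 on the log2 scale between the 2 arrays of pigs 1 and 3; the pairing rests on the labels.

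The 22 gene lists and 9 sets of cell type markers were written from textbook knowledge before the data were examined, as were the main test, the rule for named genes and most of the alternatives. Lists with at least 5 measured members (29) were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Members of each list were also adjusted over the list alone. The named genes are CD14 and CD163; in each direction up to 14 called genes with the largest difference and the same sign in all pigs, or, with fewer calls, those with the smallest p up to 8; the up to 4 members of each list with the smallest p and any called member with the largest difference; and genes whose probe sets disagree in direction. BANK1, FN1, CXCL10, IL1R2, PGLYRP1, HBB, CCR2, CD36, F13A1, VCAN, LYZ and CIITA fall outside this rule and were named after their values were seen.

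The alternatives were the pig as a fixed or random block, trended robust variance, array weights, removal of a share of 0.3333 or 0.5 of probe sets with the lowest signal, quantile normalization, median centring, other thresholds, the mean of all probe sets per gene, and omission of each pig and each array. Added after the data were seen were the single arrays, array weights and the removal of 0.5 of probe sets for the lists, the counts at an unadjusted p and of genes called over their own list alone, the background control signal as a covariate and the omission of the 2 arrays with the highest background. The functions were tested on simulated data with 50 of 47722 probe sets changed at each size: without the block, 4%, 46%, 62% and 82% of differences of 1, 2, 3 and 4 on the log2 scale were recovered, with 1 false call, and with the block 0% at each size. With 1 list shifted by 1 on the log2 scale, camera at either correlation and fry called that list and 0 others. Simulated genes were independent of each other. Figures were drawn with matplotlib 3.10.9.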

Results

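Gene expression was measured in porcine blood monocytes sorted by flow cytometry into 2 populations from each of 3 piglets, 8 weeks of age. One population carried low CD14 and high CD163 at the surface (CD163high) and the other high CD14 and low CD163 (CD163low). CD14 is a co-receptor for bacterial lipopolysaccharide and CD163 is the scavenger receptor for complexes of haemoglobin with haptoglobin. Each population of each pig was hybridised to 1 porcine Affymetrix array, which gave 6 arrays, 3 per population, and the comparison asked which transcripts differed between the 2 populations. Differences are given on the log2 scale as CD163high minus CD163low, with the standard error of the limma fit, and group means as mean ± SD over n = 3 arrays. The small number of arrays limits the precision of every value.

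The brightest probe set of each of the 2 antigens used for the sort had the direction of the gate in all 3 pigs, and a second, dimmer CD163 probe set had it in pigs 1 and 2 only. The CD163 probe set with the highest signal had a mean log2 signal of 7.92 ± 0.29 (SD, n = 3) in CD163high and 5.89 ± 0.82 in CD163low monocytes, a log2 difference of 2.03 ± 0.43 (SE) or 4.07-fold, with differences of 3.20, 1.81 and 1.07 in pigs 1, 2 and 3. The second CD163 probe set had a log2 difference of 1.06 ± 0.44, with 2.23, 1.00 and -0.056 in the 3 pigs, and did not pass over all probe sets. Its signal in CD163low of pig 1 (3.14) lay under the mean of that array's background controls, so that the sizes of its differences are uncertain. CD14 had a mean of 5.22 ± 0.80 in CD163high and 6.29 ± 0.53 in CD163low monocytes, a log2 difference of -1.07 ± 0.47, and -1.93, -0.25 and -1.02 in the 3 pigs. Adjusted over the list alone, which held these 2 antigens, CD163 passed (limma adjusted p = 0.00562) and CD14 did not (limma adjusted p = 0.0608). With the pig as a block CD14 passed as well (limma adjusted p = 0.0369). Over all probe sets neither passed.

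The genes with the smallest p were of mixed kinds, and none of them passed the test over the whole array. The 8 genes with the smallest p among those higher in CD163high monocytes were PRDX1, a peroxiredoxin (log2 difference 1.56 ± 0.21), the probe set annotated ssc-mir-29c (4.19 ± 0.33 against 2.69 ± 0.15, the latter at the level of the background controls), LGMN, the lysosomal protease legumain (2.61 ± 0.39), EHHADH, an enzyme of peroxisomal fatty acid oxidation (1.67 ± 0.28), RPLP2, IFI30, SLA-DRA and KMO, kynurenine 3-monooxygenase (1.69 ± 0.32). Among those lower in CD163high monocytes they were CXCR2, a chemokine receptor (-2.66 ± 0.41), CXCL8, listed as IL8 and encoding a ligand of CXCR2 (-3.36 ± 0.53), LOC100515345 (-3.10 ± 0.52), the cytokine gene IL18 (-1.79 ± 0.33), POU2F1, a transcription factor (-0.97 ± 0.18), LY6G5B (-0.96 ± 0.18), SAMSN1 (-1.93 ± 0.36) and TGM6, a transglutaminase (-0.84 ± 0.16). All 16 had the same direction in the 3 pigs, but the 2 groups did not overlap for any of them, which fixes the direction in each pig. This came with the choice by smallest p and is no separate support. Of the 4 probe sets of EHHADH and the 2 of LY6G5B, 1 each had the opposite direction to the value given.

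Across the 47722 probe sets tested, 0 passed an adjusted p of 0.05 in limma, and 1235 had an unadjusted p under 0.05 (587 higher and 648 lower in CD163high), where 2386.1 would be reached by chance. With the pig as a block limma called 0 probe sets and 1917 had an unadjusted p under 0.05. Groups did not overlap for 6.29% of the probe sets, against 10% by chance for 3 arrays against 3, and 22.4% had the same direction in all 3 pigs, against 25% by chance. In simulated data with the spread of these arrays, the fit without the block recovered 46% of differences of 2 on the log2 scale. It recovered 82% of differences of 4, and the fit with the block recovered 0%. The simulated probe sets were independent of each other, and 5.43% of the unchanged ones had an unadjusted p under 0.05 in limma without the block. In the real data fewer did than by chance, so these shares need not hold there. The count of probe sets with an unadjusted p under 0.05 was 772 without pig 1, 820 without CD163high of pig 1, 784 without CD163low of pig 3, 2202 without CD163low of pig 2 and 2400 without CD163high of pig 3.

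The largest source of variation between the arrays was not the gate. The first principal component held 55.2% of the variance, and placed CD163high at -41.5, -80.6 and 97.2 and CD163low at 88.3, -92.3 and 28.9 in pigs 1, 2 and 3. The mean log2 signal of the 69 background control probe sets was 2.82, 2.97 and 3.67 in CD163high and 3.29, 2.60 and 3.06 in CD163low monocytes in the same order. The number of probe sets brighter than every background control ranged from 676 in CD163high of pig 3 to 6700 in CD163low of pig 2. This number rests on the brightest control of each array, at a log2 signal of 8.38 and 5.76 in these 2 arrays. Of the genes named by the rule in these comparisons, ssc-mir-29c, EHHADH, IL18, GPNMB, C1QC, NDUFA1 and LEF1 had a signal under the mean of the background controls on at least 1 array. The sizes of their differences are therefore uncertain.

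**Figure D1:**
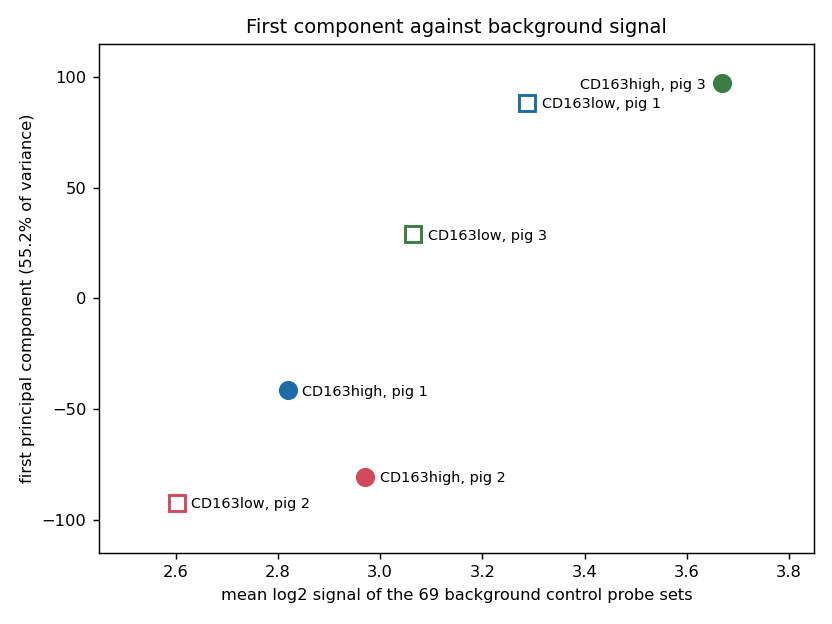
First principal component of the 47722 tested probe sets (y axis, arbitrary units) against the mean log2 signal of the 69 background control probe sets (x axis), 1 point per array, with colours for pigs, filled circles for CD163high and open squares for CD163low. The gates overlap on both axes, and CD163low of pig 2 and CD163high of pig 3 lie at opposite ends.

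Genes known from human blood to mark classical, CD14-high monocytes were lower as a group in CD163high monocytes. The 28 measured members of this list had a median log2 difference of -0.69, with medians of -0.46, -0.23 and -0.82 in pigs 1, 2 and 3, and limma's camera test called the list lower (adjusted p = 5.89e-09). The call was lost with an estimated correlation (camera adjusted p = 0.189 with an estimated correlation). Of the 28, 13 were lower and 1 was higher in all 3 pigs, 0 passed over all probe sets, and 3 passed adjusted over the list alone, all lower, while 25 did not pass. These were CXCR2, with means of 5.35 ± 0.80 in CD163high and 8.01 ± 0.22 in CD163low monocytes (limma adjusted p = 0.0148), S100A8, a calcium-binding alarmin (log2 difference -1.47 ± 0.30, limma adjusted p = 0.0331), and S100A12 of the same family (-0.95 ± 0.21, limma adjusted p = 0.0353). Other, dimmer probe sets of CXCR2 had log2 differences of -1.04 ± 0.27 and -1.27 ± 0.97, the last with 0.077 in pig 2. The thrombospondin gene THBS1 had a difference of -1.40 ± 0.41 and did not pass without the block. Another 14 members had differing signs between the pigs. Among these CCR2 had a log2 difference of 0.96 (2.3, 1.2 and -0.54 in pigs 1, 2 and 3). CD36 had 0.51, F13A1 0.43, VCAN -0.096 and LYZ -0.036, so that the shift was not shared by all classical markers. CD14, a sort antigen, is also a member of the list. With the pig as a block 5 members passed, all lower, which were CXCR2, S100A8, THBS1 (limma adjusted p = 0.0462), the interleukin-1 decoy receptor gene IL1R2 (0.0216) and the granulocyte colony-stimulating factor receptor gene CSF3R (0.0342), and S100A12 did not pass (0.0577). The median was -0.44 without CD163low of pig 3 and -0.43 with the mean of all probe sets per gene or on the 4 arrays with the lowest background, and the list was still called. Markers of neutrophils, B cells, NK cells and platelets were lower as sets in the same direction, with medians of -0.11, -0.42, -0.34 and -0.36 (camera adjusted p = 0.468, 0.468, 0.641 and 0.189 with an estimated correlation). Of the 12 neutrophil markers 4 are also members of the classical list.

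Inflammatory cytokines and chemokines were also lower as a group in CD163high monocytes. The 26 measured members had a median log2 difference of -0.36 and were called lower by camera (adjusted p = 2.31e-05), a call lost with an estimated correlation (camera adjusted p = 0.291 with an estimated correlation). Adjusted over the list alone, 3 members passed, all lower, and 23 did not. CXCL8 (IL8), a chemoattractant of neutrophils, was 10.2-fold lower, at 5.10 ± 0.34 against 8.46 ± 1.05 (limma adjusted p = 0.0159). A second probe set of CXCL8, near the level of the background controls, had a log2 difference of -0.27 ± 0.15. IL18 was lower, at 3.55 ± 0.56 against 5.35 ± 0.33 (limma adjusted p = 0.0177). No fold is given for it, since its signal in CD163high of pig 3 (2.93) lay under the mean of that array's background controls (3.67). PTGS2, the inducible cyclooxygenase, was 3.00-fold lower (limma adjusted p = 0.0177). TGFB1 had a log2 difference of -0.96 ± 0.34 and did not pass. With the pig as a block the chemokine gene CXCL10 passed as well, in the opposite direction (log2 difference 2.36, limma adjusted p = 0.0218). The list was still called, with another median, without pig 3 (-0.12), CD163high of pig 1 (-0.58) or pig 2 (-0.19), and CD163low of pig 1 (-0.20), pig 2 (-0.58) or pig 3 (-0.19).

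**Figure D2:**
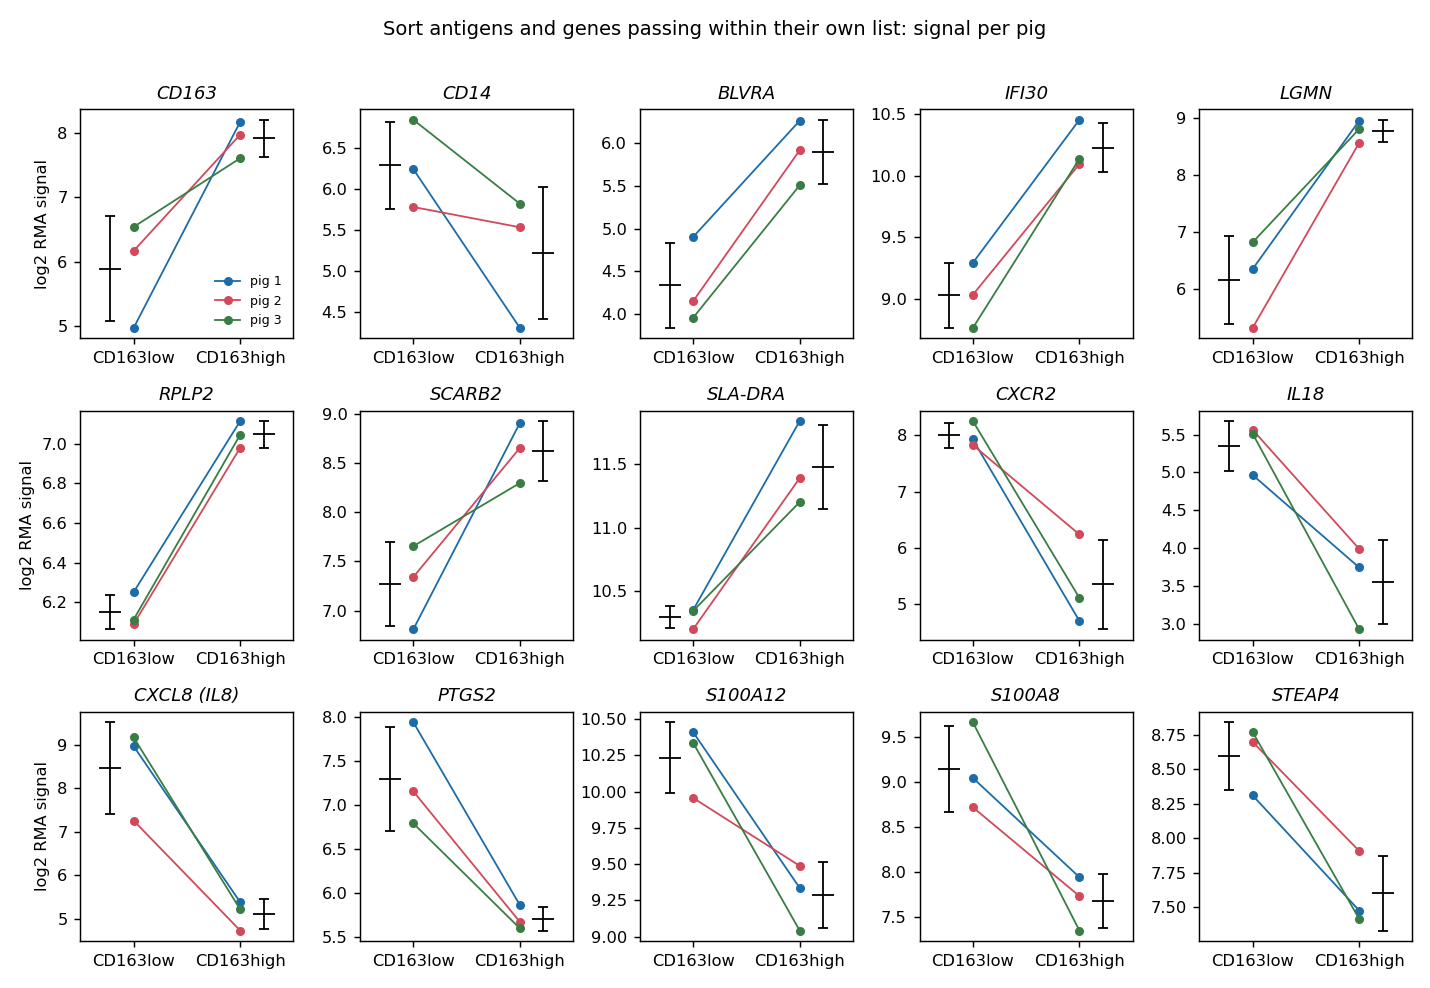
Log2 RMA signal (y axis, a separate scale per panel) of the 2 sort antigens and the other genes that passed adjusted over the list alone, in CD163low and CD163high monocytes (x axis), with 1 line per pig and the mean ± SD of the 3 arrays beside each group. Each of the 15 genes shows 1 direction in all 3 pigs, with CXCL8 (IL8) the widest gap, at a log2 difference of -3.36. The choice of the genes by p or as sort antigens favours a shared direction, which is no separate support.

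MHC class II antigen presentation genes were higher as a group in CD163high monocytes. The 17 measured members had a median log2 difference of 0.79, with 1.09, 0.86 and 0.31 in pigs 1, 2 and 3, and camera called the list higher (adjusted p = 2.70e-08), which was lost with an estimated correlation (camera adjusted p = 0.117 with an estimated correlation). Of the 17, 9 were higher and 1 was lower in all 3 pigs, and 7 had differing signs. The 1 lower member was CIITA, with a log2 difference of -0.15, which did not pass. Adjusted over the list alone 3 members passed and 14 did not. SLA-DRA, the alpha chain of the porcine class II molecule DR, had means of 11.48 ± 0.33 and 10.29 ± 0.086 (limma adjusted p = 0.00717). IFI30, a lysosomal thiol reductase, was 2.30-fold higher and LGMN was 6.10-fold higher, each with a limma adjusted p of 0.00717. The beta chain gene SLA-DRB1 had a log2 difference of 1.80 ± 0.61 and did not pass. The list median was 0.49 without CD163low of pig 1, 0.36 with array weights and 0.45 with the mean of all probe sets per gene, and the list was still called.

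Lysosome and phagocytosis genes were higher as a group, with a median log2 difference of 0.30 over 27 members (camera adjusted p = 0.000129, and adjusted p = 0.189 with an estimated correlation). The medians were 0.47, 0.66 and 0.073 in pigs 1, 2 and 3. Of the members 12 were higher and 1 was lower in all 3 pigs, and 14 had differing signs. LGMN and CTSS are members of the MHC class II list too, so the calls of these lists are not fully separate. LGMN (limma adjusted p = 0.0128) and SCARB2, a lysosomal membrane receptor (log2 difference 1.35 ± 0.28, limma adjusted p = 0.0369), passed adjusted over the list alone, and 25 members did not. SCARB2 no longer passed with the pig as a block (limma adjusted p = 0.0995), and the list median was 0.19 without CD163high of pig 2 and 0.17 with the mean of all probe sets, still called in both. Among 23 genes of haem and iron handling camera made no call (adjusted p = 0.0674), but 3 members passed adjusted over the list alone, each with a limma adjusted p of 0.0291. CD163, itself a sort antigen, and BLVRA, which encodes biliverdin reductase (1.56 ± 0.32), were higher and STEAP4, a metalloreductase gene, was 1.99-fold lower. Of these BLVRA alone passed with the pig as a block (limma adjusted p = 0.0145).

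Ribosomal protein and respiratory chain genes were each higher as a group in CD163high monocytes, although few single members passed. The 41 cytosolic ribosomal protein genes had a median log2 difference of 0.56 (camera adjusted p = 2.58e-12, and adjusted p = 0.189 with an estimated correlation), with 22 members higher and 1 lower in all 3 pigs. The medians were 0.90, 0.35 and 0.17 in pigs 1, 2 and 3, and the median was 0.21 without pig 1 and 0.34 without CD163low of pig 1, and 0.29 with the mean of all probe sets, with the list still called. RPLP2, at 7.05 ± 0.067 and 6.15 ± 0.087, passed adjusted over the list alone (limma adjusted p = 0.0397), and did not with the pig as a block (limma adjusted p = 0.0847). RPLP0 had a difference of 1.34 ± 0.32 and did not pass, as did 39 other members. The 26 oxidative phosphorylation genes had a median of 0.41 (camera adjusted p = 2.43e-06, and adjusted p = 0.215 with an estimated correlation), with medians of 0.96, 0.41 and 0.086 in the 3 pigs. The median was 0.23 without pig 1 and 0.64 without pig 3 or its CD163low array, 0.63 without the dimmest 0.5 of probe sets and 0.65 on the 4 arrays with the lowest background, and the list was still called. Adjusted over the list alone limma called 0 of its members, and 3 had an unadjusted p under 0.05. ATP5A1, a subunit of the ATP synthase, had a difference of 1.85 ± 0.67 and SDHA, a subunit of succinate dehydrogenase, 0.73 ± 0.22. Of the 26 members 10 were higher and 1 lower in all 3 pigs, and 15 had differing signs. The lower one was NDUFA1, a subunit of complex I, at -0.56 ± 0.24. Its difference ran from -0.80 to -0.29 when a pig or an array was left out. Its signal in CD163high of pig 3 (3.49) lay under the mean of that array's background controls (3.67).

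**Figure D3:**
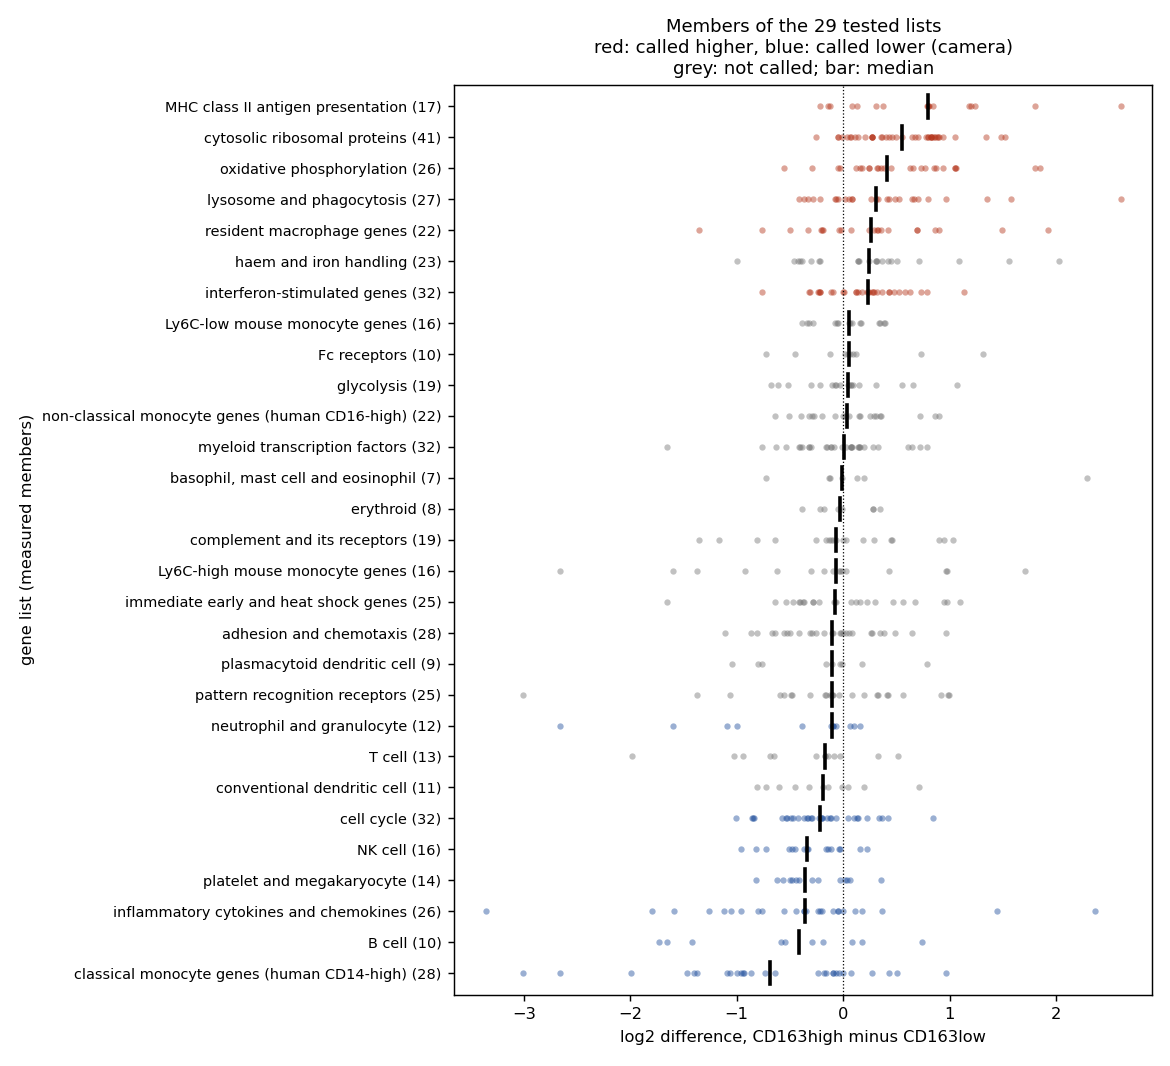
Log2 difference, CD163high minus CD163low (x axis), of each measured member (points) of the 29 tested lists (y axis, with the number of members), with black bars for medians. Red and blue lists were called higher and lower by camera and grey ones were not, and the medians run from -0.69 for classical monocyte genes to 0.79 for MHC class II antigen presentation.

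Interferon-stimulated genes and resident macrophage genes were called higher by camera with smaller shifts, and their calls depended on single pigs or arrays. The 32 interferon-stimulated genes had a median of 0.23 (camera adjusted p = 0.0264, and adjusted p = 0.596 with an estimated correlation). The call ended without pig 1 (median 0.016) or pig 2 (0.13), CD163high of pig 1 (-0.023) or pig 2 (0.19), and CD163low of pig 2 (0.15). The list stayed called with medians of 0.38 without pig 3, 0.55 without its CD163high array, 0.13 without its CD163low array, 0.46 with array weights and 0.62 on the 4 arrays with the lowest background. BST2, an antiviral membrane protein gene, had a difference of 1.14 ± 0.39. Adjusted over the list alone limma called 0 members, and 1 had an unadjusted p under 0.05. The 22 resident macrophage genes had a median of 0.27 (camera adjusted p = 0.0242, and adjusted p = 0.468 with an estimated correlation), which was not called with the pig as a block (camera adjusted p = 0.0659), nor without pig 2 (median 0.18) or pig 3 (0.10), CD163low of pig 2 (0.22) or pig 3 (0.20), and CD163high of pig 3 (0.11). Its members went both ways. The receptor kinase gene AXL had a difference of 0.87 ± 0.24, GPNMB 1.92 ± 0.59 (3.67, 1.59 and 0.51 in pigs 1, 2 and 3) and the complement component gene C1QC 0.90 ± 0.30, whereas VSIG4, a complement receptor gene, had -1.36 ± 0.30. Adjusted over the list alone limma called 0 members, and 3 higher and 1 lower had an unadjusted p under 0.05. Cell cycle genes were called lower (median -0.21 over 32 members, camera adjusted p = 0.0132, and adjusted p = 0.596 with an estimated correlation), with TYMS at -0.84 ± 0.23 and MKI67 at -0.85 ± 0.28. Limma called 0 of them adjusted over the list alone, and 2 had an unadjusted p under 0.05. The cell cycle list was not called without pig 2 (median -0.20) or pig 3 (-0.28), CD163low of pig 2 (-0.092) or CD163high of pig 3 (-0.14), and was called at -0.39 without CD163high of pig 2 and -0.37 without CD163low of pig 3.

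Other monocyte lists were not called by camera in the main setting with all 6 arrays. With quantile normalization the Ly6C-high and adhesion lists were called lower, and with median centring the Ly6C-high list was. The 22 genes of human non-classical, CD16-high monocytes had a median log2 difference of 0.039 (camera adjusted p = 0.633), with CDKN1C, a cell cycle inhibitor gene, at 0.87 ± 0.33 and PECAM1 at -0.64 ± 0.41. Genes of Ly6C-high mouse monocytes had a median of -0.066 over 16 members (camera adjusted p = 0.0665), although fry called them for changes in either direction (adjusted p = 0.0370, and 0.0826 with the pig as a block). In this list CXCR2 passed adjusted over the list alone (limma adjusted p = 0.00846), with the fibronectin gene FN1 passing as well, in the higher direction, with the pig as a block (log2 difference 1.71, limma adjusted p = 0.0124). Those of Ly6C-low mouse monocytes had a median of 0.058 and a mean of 0.030 with a camera direction of lower (adjusted p = 0.985). Camera made no call for pattern recognition receptors (median -0.11), where TREM1, an amplifier of inflammatory signals, had a difference of -3.01 ± 1.03 with -6.41 in pig 3, nor for complement (-0.064, called by fry for changes in either direction, adjusted p = 0.0370, and 0.0657 with the block), Fc receptors (0.055), myeloid transcription factors (0.0093, mean -0.059), adhesion and chemotaxis (-0.10), glycolysis (0.042, with a camera direction of lower) and immediate early and heat shock genes (-0.081). Camera adjusted p-values of these 7 lists lay between 0.105 and 0.985, and limma called 0 members of each adjusted over the list alone, where 0 to 3 members had an unadjusted p under 0.05. Within glycolysis PFKP had a difference of -0.67 ± 0.18.

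Of the 9 sets of markers for other blood cells, camera called 4 lower in CD163high monocytes and made no call on the other 5. B cell markers had a median of -0.42 over 10 genes (camera adjusted p = 0.0242, and adjusted p = 0.468 with an estimated correlation), with 6 lower and 1 higher in all 3 pigs. The 1 higher member was BANK1, at 0.74 ± 0.55, which did not pass. Among the 6 were MS4A1 at -1.73 ± 1.05, and EBF1 at -1.65 ± 0.61 and TNFRSF13C at -1.42 ± 0.49, the last 2 of which passed adjusted over the list alone with the pig as a block only (limma adjusted p = 0.0282 and 0.0371). NK cell markers had a median of -0.34 (camera adjusted p = 0.0242, and adjusted p = 0.641 with an estimated correlation). Platelet markers had a median of -0.36 (camera adjusted p = 0.00598, and adjusted p = 0.189 with an estimated correlation). Neutrophil markers had a median of -0.11 and a mean of -0.57 (camera adjusted p = 0.00769, and adjusted p = 0.468 with an estimated correlation), with CXCR2 the 1 member that passed adjusted over the list alone (limma adjusted p = 0.00635), CHI3L1 at -1.60 ± 0.57 and CSF3R at -1.09 ± 0.56. With the pig as a block CSF3R passed too (limma adjusted p = 0.022). The camera calls of these 4 sets ended when single pigs or arrays were left out. That of B cells ended without pig 3 (median -0.48), CD163high of pig 1 (-0.16) or pig 3 (-0.39), or CD163low of pig 2 (-0.085). That of NK cells ended without pig 1 (-0.17), pig 3 (-0.26), CD163high of pig 1 (-0.029) or pig 3 (-0.17), or CD163low of pig 2 (-0.16). That of platelets ended without pig 1 (-0.14), pig 3 (-0.31) or its CD163high array (-0.34), and that of neutrophils without pig 1 (-0.042). Without CD163high of pig 2 the calls stood at -0.71 for B cells and -0.52 for NK cells, and without CD163high of pig 1 at -0.24 for platelets. The neutrophil median ran from -0.36 without CD163low of pig 2 to -0.030 without CD163low of pig 1, and was -0.69 without the dimmest 0.5 of probe sets. Array weights and the background covariate ended the B cell, NK cell and platelet calls. The 4 arrays of lowest background ended those of B cells and platelets, and removal of the dimmest 0.3333 of probe sets ended that of NK cells. T cell markers had a median of -0.17 and were called with the pig as a block only (camera adjusted p = 0.194 without and 0.0165 with the block), where LEF1 passed adjusted over the list alone (limma adjusted p = 0.0455). The blocked call of T cells was lost too (camera adjusted p = 0.418 with an estimated correlation and the block). Erythroid (-0.030), conventional dendritic cell (-0.19), plasmacytoid dendritic cell (-0.10) and basophil, mast cell and eosinophil markers (-0.014, mean 0.23) were not called, with KIT, the stem cell factor receptor gene, at 2.29 ± 0.86, with 4.60 in pig 1 and 0.76 in pig 3, and 1.13 without pig 1. EIF1AY, the 1 measured gene of the Y-linked list, had differences of 4.07, 0.054 and -2.31 in pigs 1, 2 and 3.

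In all, camera called 13 of the 29 tested lists, 6 higher and 7 lower, and 0 with an estimated correlation. The 13 ranged from 8 to 17 when a pig or an array was left out, and became 8 with array weights or the background covariate. Fry called 0 for a shift in 1 direction and 5 for changes in either direction, or 0 with the pig as a block. The 5 were the classical, Ly6C-high, MHC class II, inflammatory and complement lists. Adjusted over the list alone, limma called 14 of the 517 genes in any list, 7 higher and 7 lower, and 19 with the pig as a block, of which 10 were shared. Sort antigens are among them: CD163, and with the block CD14 too, had a direction that the gate favours. These counts were not adjusted for the number of lists: over all 517 genes together 0 passed in limma with or without the block, with a smallest limma adjusted p of 0.105, and 59 had an unadjusted p under 0.05, or 89 with the block. The 14 became 1 without pig 1, 3 without pig 3, 5 without CD163high of pig 1, 9 without CD163high of pig 2 and 8 without CD163low of pig 3.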

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

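The settings on background signal, the single arrays, array weights and removal of 0.5 of probe sets for lists, the mean of probe sets for named genes other than CD14 and CD163, and all settings for the counts at an unadjusted p and for calls adjusted over the list alone were chosen after the data were seen. The count of called probe sets was 0 in limma under every setting run, including a threshold of 0.1; with the pig as a block the simulated data gave 0 calls too, so that 0 says nothing on stability. CD163 kept a positive and CD14 a negative log2 difference in each setting, from 1.44 to 2.50 and from -1.48 to -0.61 when a pig or an array was left out. Of the 111 named genes, 102 kept their sign in all settings. The lists of classical monocyte, inflammatory, MHC class II, lysosome, ribosomal and oxidative phosphorylation genes were called in 18 of 21 settings; the other 3 were the estimated correlation and fry with and without the block, where 0 lists were called. The other 7 called lists were called in 8 to 17 of 21. Besides those 3 settings and the omissions given in the report, array weights ended the calls of B cells (-0.44), NK cells (-0.24), platelets (-0.33), resident macrophage genes (0.18) and cell cycle, and so did the background covariate (-0.32, -0.24, -0.34, 0.18 and -0.15). The 4 arrays with the lowest background ended those of B cells (-0.60), platelets (-0.25), resident macrophage genes (0.17) and cell cycle (-0.14). Without the dimmest 0.3333 of probe sets NK cells (-0.33), without the dimmest 0.5 cell cycle (-0.20), with quantile normalization interferon-stimulated genes (0.17) and with the mean of all probe sets resident macrophage genes (0.15) were not called. With the replicate block the count of called lists stayed at 13, with T cell markers in place of resident macrophage genes, and no other list call changed. Lists not called in the report were called lower when a pig or an array was left out: T cells without pig 2 (-0.63), CD163low of pig 1 (-0.49) or pig 3 (-0.39), or CD163high of pig 2 (-0.96), adhesion without pig 2 (-0.25), CD163low of pig 1 (-0.26) or CD163high of pig 2 (-0.29), Ly6C-high genes without pig 1 (-0.28), its CD163high (-0.20) or CD163low array (-0.15) or CD163high of pig 2 (-0.11), conventional dendritic cells without pig 2 (-0.49) or its CD163high (-0.14) or CD163low array (-0.36), and erythroid without CD163high of pig 2 (-0.55). Haem and iron handling was called higher without pig 1 (0.13) or its CD163high array (0.21). With all arrays, Ly6C-high genes were called with quantile normalization (-0.18) or median centring (-0.026), adhesion with quantile normalization (-0.18) and conventional dendritic cells without the dimmest 0.5 of probe sets (-0.39).

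Counts moved as follows, and the cause was not tested unless fewer probe sets or arrays were fitted. The 1235 probe sets with an unadjusted p under 0.05 became 1917 with the replicate block, 1875 with the pig as a random block, 8884 with array weights, 785 and 604 without the dimmest 0.3333 and 0.5 of probe sets, and 4719 with the background signal as a covariate. The 14 genes called over their own list alone became 5 with a trended robust variance, 109 with array weights, 9 without the dimmest 0.5 and 55 with the background covariate. The 13 called lists became 8 with array weights and 8 with the background covariate. The array weights gave CD163low of pig 3 a weight of 5.79 and the others between 0.38 and 1.88, so that setting leaned on 1 array. When an array or a pig was left out, probe sets with an unadjusted p under 0.05 ranged from 772 (without pig 1) to 2400 (without CD163high of pig 3), with 820 without CD163high of pig 1, 2202 without CD163low of pig 2 and 784 without CD163low of pig 3. Called lists ranged from 8 (without pig 3 or its CD163high array) to 17, and genes called over their own list alone from 1 (without pig 1) to 17, with 3 without pig 3, 5 without CD163high of pig 1, 9 without CD163high of pig 2 and 8 without CD163low of pig 3.

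Directions reversed as follows, each without a call in the reversed direction at an adjusted p of 0.05, and the cause was not tested. The cell cycle and interferon-stimulated lists had been called in the other direction. For lists the direction is that of the set test and the value the median log2 difference. With array weights these were CDK1 0.10, EPX -0.14 and HEMGN 0.30, and the lists for basophils -0.14, cell cycle 0.024, erythroid 0.35, Fc receptors -0.20, immediate early genes 0.039, transcription factors -0.18 and non-classical monocytes -0.18. With arrays centred on the median they were basophils 0.026, complement -0.025 and transcription factors 0.049. With the background covariate they were HEMGN 0.041, basophils -0.17, complement -0.092, erythroid 0.25, Fc receptors -0.0086, glycolysis -0.016, immediate early genes -0.13, transcription factors -0.13 and non-classical monocytes -0.0046. With fry they were basophils -0.014 and transcription factors 0.0093, and with fry and the replicate block also erythroid -0.030, Fc receptors 0.055, glycolysis 0.042 and Ly6C-low genes 0.058. With the replicate block in camera they were erythroid -0.030, glycolysis 0.042, Ly6C-low genes 0.058 and transcription factors 0.0093. With the mean of all probe sets they were PPARG -0.13, complement -0.056, erythroid -0.030, Fc receptors 0.0038, glycolysis 0.042 and transcription factors -0.15. Transcription factors were at -0.080 with quantile normalization and at 0.0093 without the dimmest 0.3333 or 0.5 of probe sets, and without the dimmest 0.5 Fc receptors were at 0.058. On the 4 arrays with the lowest background they were EPX -0.011, glycolysis 0.052, immediate early genes 0.20, non-classical monocytes -0.061 and pattern recognition receptors 0.014. Over the omissions of a pig or an array the range crossed 0 for AHSP (-0.75 to 1.38), EIF1AY (-1.13 to 2.14), EPB42 (-0.11 to 0.69), EPX (-0.019 to 0.34), HEMGN (-1.0 to 0.65), IRF8 (-1.50 to 0.0080), PPARG (-0.048 to 0.78) and SLC4A1 (-0.47 to 0.029). The test direction reversed in at least 1 omission for the lists of non-classical monocytes (-0.12 to 0.26), Ly6C-low genes (-0.10 to 0.21), interferon-stimulated genes (-0.023 to 0.55), pattern recognition receptors (-0.25 to 0.32), complement (-0.13 to 0.047), Fc receptors (-0.088 to 0.18), transcription factors (-0.27 to 0.11), adhesion (-0.29 to 0.034), glycolysis (-0.22 to 0.095), immediate early genes (-0.32 to 0.19), T cells (-0.96 to 0.20), erythroid (-0.55 to 0.63) and basophils (-0.19 to 0.21), and the median of plasmacytoid dendritic cells crossed 0 (-0.35 to 0.045) with no reversal of the test. Among genes that did not pass without the block, differences also moved by over 1.5 times over the omissions for CHI3L1 (-2.09 to -1.05), CSF3R (-1.56 to -0.67), C1QC (0.53 to 1.22), GPNMB (1.05 to 2.63), KIT (1.13 to 3.13), LEF1 (-3.30 to -0.86), MS4A1 (-2.80 to -0.95), NDUFA1 (-0.80 to -0.29), PECAM1 (-1.08 to -0.16), SLA-DRB1 (1.13 to 2.29), TNFRSF13C (-1.73 to -0.87) and TREM1 (-4.17 to -1.31). Neutrophil markers, still called, had medians of -0.46 with array weights, -0.068 with median centring, -0.23 with the background covariate and -0.19 on the 4 arrays with the lowest background, and over the omissions they ranged from -0.36 to -0.030. B cell markers had -0.73 with the mean of all probe sets, still called. AHSP, CDK1, EPB42, EPX, HEMGN and SLC4A1 had a signal under the mean of the background controls on at least 1 array. Signal over background limits dim genes most in CD163high of pig 3, where the mean background was highest (3.67). There 676 probe sets exceeded all background controls, a count that rests on the brightest control (8.38).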

Other observations

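Pig 2 stood apart from the others in lymphocyte and red cell transcripts, in both of its arrays. The mean log2 signal of the T cell markers was 6.80 and 6.85 in CD163high and CD163low of pig 2 and between 4.31 and 5.16 in the other arrays, and that of the erythroid markers 5.82 and 5.79 against 3.31 to 3.55. B cell markers (6.36 and 6.75 against 5.30 to 6.07) and NK cell markers (5.08 and 5.24 against 4.15 to 4.68) were higher in pig 2 too. Platelet, neutrophil, conventional dendritic and plasmacytoid dendritic cell markers did not set pig 2 apart (platelets 3.96 and 3.97, against 3.73 to 4.29). The log2 signal of HBB, a globin gene, was 10.78 and 10.50 in CD163high and CD163low of pig 2 and between 3.42 and 4.64 in the 4 other arrays. CD3E, a T cell receptor component gene, was at 7.08 and 7.06 in pig 2 and between 3.78 and 5.40 elsewhere, and the B cell gene MS4A1 was at 8.45 and 9.30 in pig 2 and between 4.77 and 8.00 elsewhere. These sets, HBB, CD3E and MS4A1 were singled out after their values were seen, and no explanation was tested. EIF1AY, the 1 measured Y-linked gene, was at 9.17 and 9.12 in pig 2 but at 9.16 and 5.09 in CD163high and CD163low of pig 1 and at 4.57 and 6.88 in those of pig 3, although the labels give both arrays of a pig to 1 animal; a mix-up of samples was not tested, and no second Y-linked gene was measured.

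The tests below were chosen after the values they bear on were seen, except those on the brightness of list members and on the lists and list genes called by other splits. The first pattern is the spread of the arrays along the first component, which across the 6 arrays followed the mean background control signal, with Pearson's r = 0.89 (exact permutation p = 0.00972) and Spearman's rho = 0.94 (exact permutation p = 0.0167), the only relation of this kind computed, and r was 0.85 over the 4 arrays left without the 2 farthest. The gate does not account for it, since the 2 gates overlapped over 89.1% of the range, and if the labels' pairing holds neither does the pig alone, since the 2 arrays of a pig lay 68.5% of the whole range apart in pig 1, against 6.20% in pig 2. The argument against the pig rests on those labels. EIF1AY was at 9.12 to 9.17 in the 3 arrays at the negative end and at 4.57 to 6.88 in the others. In those others it fell from 6.88 to 5.09 and 4.57 as the mean background rose from 3.06 to 3.29 and 3.67. EIF1AY therefore does not separate an exchange of samples between pigs from flattened signal, and an exchange stays open. A candidate explanation is a difference in hybridisation or RNA between arrays that raises background and flattens signal, which these values do not separate.

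The second pattern is the lower signal of classical monocyte and inflammatory genes in CD163high monocytes. Background is argued against as the whole cause. With it as a covariate the median of the classical list was -0.71, against -0.69 without it. The list stayed called by camera (adjusted p = 0.00290, within a range over the alternatives of 6.57e-12 to 0.348). That call alone could not exclude background, since camera does not measure the spread between arrays. Neutrophils left in the CD163low sort could raise CXCR2 and CXCL8 there, although the isolation of mononuclear cells and the freezing and thawing act against them. Whether the CD14 and CD163 gate kept neutrophils out of the CD163low sort was not tested. Of 12 measured neutrophil markers 4 are also in the classical list, and the median of the 8 others was -0.082. The 2 explanations cannot be told apart from this, because 6 of the 8 had a mean log2 signal under 5 and the 2 brighter ones went apart, CHI3L1 at -1.60 and PGLYRP1 at 0.061; a difference between the monocyte populations themselves stays open.

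The third pattern is the higher signal of antigen presentation, lysosome, ribosomal and respiratory genes in CD163high monocytes. A trend with brightness is argued against: the typical (median) random list of 10000 matched on mean signal reached at most 15.3% of a list's median, and each of the 4 medians lay above the range of 95% of its matched lists, lysosome by the least (0.30 against 0.25, percentile 99.1). With the background covariate camera called all 4 of the 4 lists higher, with medians of 0.84, 0.30, 0.71 and 0.51 in the order named. Without pig 1 it also called 4 of 4, at 0.58, 0.31, 0.21 and 0.23, against 0.79, 0.30, 0.56 and 0.41 with all arrays. Camera at the preset correlation does not measure the spread between arrays, and 1 other split of the arrays also gave 13 called lists. Kept calls therefore cannot exclude background or pig 1, and the ribosomal and respiratory medians fell without pig 1. A difference in RNA quality between the sorted fractions was not tested, and with no call at an estimated correlation the hypothesis that CD163high monocytes of these pigs express more of these genes stays open.

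Other splits of the 6 arrays into 3 and 3 bear on the counts, but 10 splits are too few for a share under 0.05. The real split called 0 probe sets in limma, which all 10 splits reach, and 1 other called 2390. That split set CD163high of pig 1 and both arrays of pig 2 against the rest. It parts the arrays at 0 on the first component, so its calls restate that structure of the arrays, which is other than the gate, and are no independent evidence of it. The real split gave 1235 probe sets with an unadjusted p under 0.05, and 6 of 10 splits gave at least as many, with 13264 the highest other. It called 13 lists with camera, which 2 of 10 splits reached, the other one also with 13, and 14 genes over their own list alone, which 3 of 10 reached, with 92 the highest other. Of these splits 4 part the 2 arrays of all 3 pigs: the real one, with 13 lists and 14 genes, and 3 others, with 1 to 7 lists and 0 genes. With the pig as a block these 3 gave 6, 9 and 1 lists and 2, 0 and 1 genes, against 13 and 19 in the real split, and 2297, 859 and 3894 probe sets with an unadjusted p under 0.05, of which 2 counts exceed the real 1917. The other 6 splits part 1 pair only.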
